A study of Arabidopsis thaliana with 4 samples.

How the data were processed

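RNA of whole 1-week-old seedlings was measured on Affymetrix ATH1 arrays, 2 for Col-0 and 2 for exo70A1-2, with genotype and replicate number taken from the sample titles. Per the labels, seed was kept cold for 3 days, sown at 75 seeds per plate on medium with 1.6% agar, and grown at 22 °C and 65% humidity in constant light. RNA was extracted with a column kit and labelled with biotin by the 3' in vitro transcription method, per the labels' protocols. The submitters' processing notes name MAS5 and GCOS, without versions. The deposited table gives 1 intensity per probe set and array on a linear scale, scaled by the authors so that the mean with 2% of probe sets trimmed at each end is 100 on every array, as the values themselves show. Scanner files and detection calls were not used here. MAS5 subtracts mismatch probes and estimates each array on its own, which makes low signals noisy.

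From this table, log2 of the signal was taken with no added constant and no further scaling, since the trimmed means of the 4 arrays were equal. The 64 control probe sets were left out of the comparison. A probe set was tested when its mean log2 signal was at or above the 40th percentile of all 22746 others, a signal of 21.9, which also serves as the dim limit, and 13648 were tested. The comparison was made with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior degrees of freedom were 6.66. Standard errors are the moderated ones of that fit.

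Probe sets were named through a probe annotation table of the array and updated through the RefSeq gene table of assembly TAIR10.1, which was used only for names and for which genes neighbour each other. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 were unnamed here, and 13436 of the first kind matched the RefSeq table. No gene was named from a probe set with several genes. The level of EXO70A1 is not reported here, since 0 probe sets were named for it.

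The test, the filter, the rule for named genes, the 38 gene lists and 17 alternatives were set before the data were examined. Genes named are the 12 largest rises and 12 largest falls by log2 fold change among probe sets of 1 gene that passed, with both mutant arrays on the same side of both Col-0 arrays and the brighter genotype at or above the 60th percentile of mean signal, 59.8. To these come up to 3 changed members of each gene list. Other genes named with their values are members of these lists that did not pass and, in the closing section, members of gene families and of lists drawn up later, all chosen after their values were seen as examples. Of 638 list entries, 87 had a probe set of 1 gene and 59 genes were tested. Lists with at least 5 tested members were tested with camera on 1 probe set per gene, the brightest, over 7213 genes, with a preset inter-gene correlation of 0.01. Neither of the 2 lists tested passed, with the preset or with an estimated correlation.

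The fit was tested on simulated arrays with normal noise around the real means of the 13648 probe sets, with genes independent. The spreads were drawn from the variance prior that limma had fitted to these data. Since the fit assumes that same model, the rates below do not show how it controls errors on real MAS5 values. With 200 changed probe sets it recovered 12.2% of 1.5-fold, 61.2% of 2-fold and 98.5% of 4-fold changes, and 4.50% of its calls were false. With 3000 changed, it recovered 57.2%, 93.1% and 100.0% of these, and 3.71% of its calls were false. With nothing changed it made 0 calls. Camera called 6% of 200 unchanged lists of 7 genes, and 100% of lists of 7 shifted by 0.5 on the log2 scale.

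The alternatives were other scalings, other filters, log2 of the signal plus 16, other variance priors, the replicate number as a block, leaving out each array, other thresholds, and for lists other set tests. Figures were drawn with matplotlib 3.10.9.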

Results

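Whole seedlings of Arabidopsis thaliana were profiled on 4 one-colour ATH1 arrays, 2 from wild-type Col-0 and 2 from the exo70A1-2 mutant in the Col-0 background. EXO70A1 encodes a subunit of the exocyst, the protein complex that tethers secretory vesicles to the plasma membrane before they fuse with it. Per the labels, the seedlings were 1 week old and had grown upright on agar plates at 22 °C in constant light. The question the design poses is which transcripts differ in level when EXO70A1 is mutated. Each array gave a signal for 22810 probe sets, and 13648 of the 22746 that are not controls were bright enough to be tested. The median signal of an array lay between 37.3 and 38.8. Across the tested probe sets, log2 signals of replicate arrays correlated at 0.980 in Col-0 and 0.987 in exo70A1-2, and those of arrays of different genotype at 0.932 to 0.955. These correlations run across probe sets, which are not independent replicates. The labels do not say whether the arrays of a genotype came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. With 2 arrays per genotype, the number of arrays limits the precision.

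The gene with the largest fitted rise in exo70A1-2 was GAT1_2.1 (AT1G15040), which encodes a glutamine amidotransferase, and the gene with the largest fitted fall was ORA47 (AT1G74930), which encodes an ERF transcription factor linked to jasmonate synthesis. Signal of GAT1_2.1 was 3.08 ± 1.38 in Col-0 and 238 ± 56.2 in exo70A1-2 (mean ± SD, n = 2 arrays here and below), at least 10.7-fold higher in the mutant. Signal of ORA47 was 240 ± 32.4 in Col-0 and 24.9 ± 13.5 in exo70A1-2, a log2 fold change of -3.38 with a standard error of 0.32, and of -2.68 with 16 added to each signal. Both superlatives cover the probe sets that carry 1 gene name and meet the rule for naming genes. Where every array of the dimmer genotype lay under the dim limit of 21.9, the fold is given as at least the ratio of the brighter genotype's mean, taken on the log2 scale, to that limit. For ORA47 only exo70A1-2 replicate 2, at 15.4, lay under it. In all, 2189 probe sets changed at an adjusted p under 0.05 (limma), 1165 of them higher and 1024 lower in exo70A1-2.

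**Figure D1:**
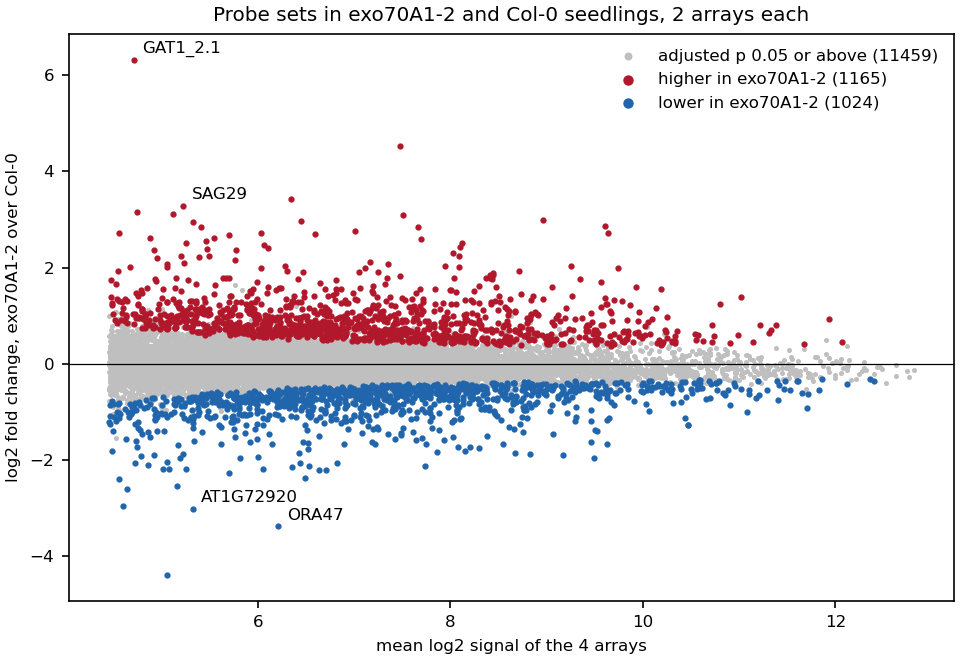
Each point is one of the 13648 tested probe sets, with its mean log2 signal over the 4 arrays on the x axis and its log2 fold change, exo70A1-2 over Col-0, on the y axis. The 1165 probe sets that were higher are red, the 1024 that were lower are blue and the others are grey. GAT1_2.1 is the highest point among the genes named.

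The 12 largest rises took in a sugar transporter, a linker histone and a ubiquitin ligase besides GAT1_2.1. The rises and the falls were ranked by fitted log2 fold change. Where a genotype was dim that value is uncertain, and so is the gene's rank against genes bright in both genotypes. SAG29 (AT5G13170), the sugar transporter SWEET15 that is known from senescing leaves, had a signal of 12.0 ± 0.159 in Col-0 and 117 ± 11 in exo70A1-2, at least 5.34-fold higher (adjusted p = 8.00e-05). AT2G21640, a gene often used as a marker of oxidative stress, was at least 4.68-fold higher, at 103 ± 14.5 in the mutant. AT5G09570, which encodes a small twin CX9C protein, was at least 3.34-fold higher, at 73.6 ± 11.8. HIS1-3 (AT2G18050), a linker histone H1 known to respond to drought, was at least 4.11-fold higher, and the RING-type ubiquitin ligase gene ATL8 (AT1G76410) at least 3.65-fold. A pair of genes annotated as lipid transfer protein-like rose as well, AT1G62510 with a log2 fold change of 2.24 (SE 0.18) and AT2G37870 with 2.16 (SE 0.21), or 1.65 with 16 added to each signal, 1 Col-0 array being dim. The remaining members of the 12 were AT5G62280 with a log2 fold change of 2.96, AT4G39675 with 2.61 (1.90 with 16 added to each signal, 1 Col-0 array being dim), AT1G55960 with 2.12, and AT1G65500, at least 3.12-fold higher. All 12 had an adjusted p of 0.000654 or less.

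The 12 largest falls took in pectin-modifying enzymes, a calmodulin-like protein and an oxidase besides ORA47. AT1G72920, which encodes a TIR-domain protein, had a signal of 115 ± 20.8 in Col-0 and 15.3 ± 8.58 in exo70A1-2, at least 5.20-fold lower in the mutant. PME61 (AT3G59010), a pectin methylesterase, fell by 1.95 on the log2 scale (SE 0.23), and AT1G60590, a pectin lyase-like protein, fell by 2.22 (SE 0.23). AT1G31690, a copper amine oxidase, fell on both of its probe sets, by 2.19 and by 1.95 on the log2 scale. On the probe sets of PME61 and of the larger AT1G31690 fall 1 mutant array was dim, and with 16 added to each signal their log2 fold changes were -1.34 and -1.45. AT4G11190, of the dirigent family, fell by 2.19. AT3G12900, the scopoletin 8-hydroxylase of coumarin synthesis, was at least 3.71-fold lower, with a signal of 81.4 ± 8.20 in Col-0 and 18 ± 3.91 in the mutant. The calmodulin-like gene AT2G41090 went from 450 ± 81.5 in Col-0 to 103 ± 20.9 in exo70A1-2. AT5G55450, annotated as a lipid transfer protein, was at least 3.27-fold lower. AT3G16670 fell by 1.88, the CCT-motif gene AT1G07050 fell by 1.77, and AT1G78020 fell by 1.73 on the log2 scale. The highest adjusted p of the 12 was 0.00594, for AT1G07050.

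**Figure D2:**
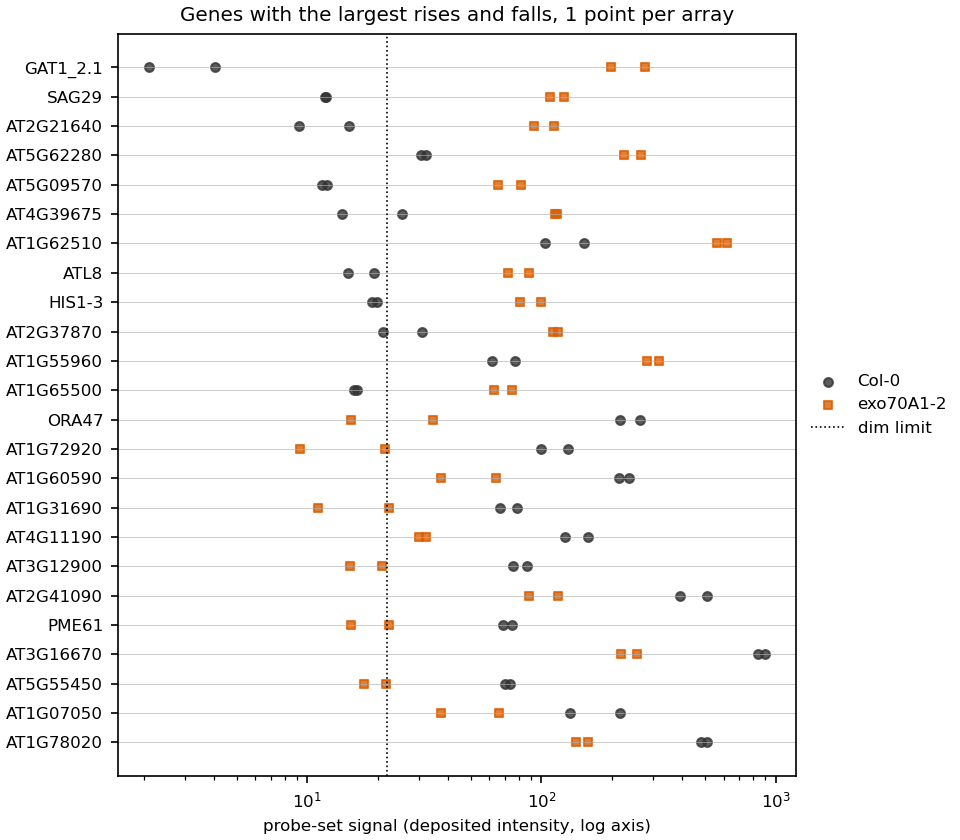
Signals on a log axis for the genes with the 12 largest rises (upper rows) and the 12 largest falls (lower rows), 1 point per array, circles for Col-0 and squares for exo70A1-2. In every row both mutant arrays lie on the same side of both Col-0 arrays, and the dotted line is the dim limit of 21.9.

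Of the genes in the lists fixed before the data were examined, 59 were tested and 10 changed, 6 higher and 4 lower in exo70A1-2, and the count was also 10 when adjusted over the list members alone, and 17 without Col-0 replicate 2. Of all 7213 named genes tested 14.1% changed, and 10 of 59 lies near that share. Of 22 listed genes of glucosinolate synthesis 2 were tested, and both fell. BCAT4 (AT3G19710), an aminotransferase of methionine chain elongation, went from 740 ± 25 to 379 ± 80.1. The glucosyltransferase gene AT2G31790 (UGT74C1) went from 296 ± 14.7 to 135 ± 9.03. In the cold and drought list 2 of 4 tested members rose, COR15A with a log2 fold change of 1.09 (SE 0.23) and the dehydrin gene LTI30 with 0.93 (SE 0.11). COR47 had a log2 fold change of -0.07 and COR15B of -0.52, and neither passed the test. In the oxidative stress list the zinc finger gene STZ (ZAT10) fell by 1.59 (SE 0.13) and the glutathione transferase gene GSTU25 rose by 0.62 (SE 0.11). Of 3 tested auxin response genes, WES1 (GH3.5), which encodes an enzyme that conjugates auxin to amino acids, rose by 0.77, while GH3.3 at 0.26 and HAT2 at 0.35 did not pass. GID1B, a gibberellin receptor gene, rose by 0.77, and GID1A at 0.25 did not pass. The calls for WES1 and GID1B ended without exo70A1-2 replicate 2, at adjusted p values of 0.0806 and 0.139, and that for GID1B also ended without exo70A1-2 replicate 1, at 0.0700, and with no filter on dim probe sets, at 0.0506.

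**Figure D3:**
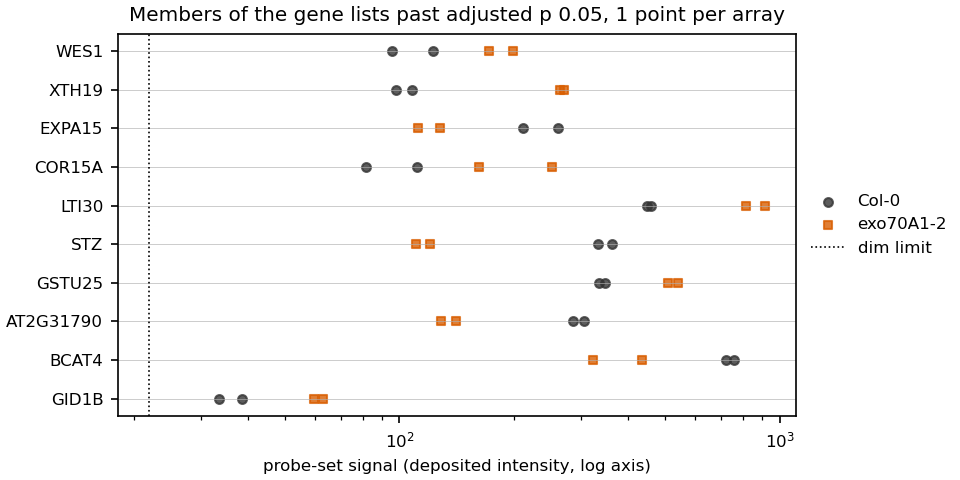
Signals on a log axis for the 10 list genes that changed, 1 point per array, circles for Col-0 and squares for exo70A1-2. XTH19 has the widest gap among those that were higher, from 103 ± 7.27 in Col-0 to 267 ± 4.43 in exo70A1-2, and the dotted line is the dim limit of 21.9.

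Of the 34 exocyst genes other than EXO70A1 in the list, 7 were tested. All were SEC or EXO84 genes, so the other EXO70 genes were not covered. None of the 7 tested genes passed the test. Their median log2 fold change was 0.06, between -0.22 for SEC10 and 0.44 for SEC15B, and the list as a whole did not pass (camera, adjusted p = 0.734). Among 7 tested expansin and xyloglucan endotransglucosylase genes of growing cells, which loosen and remodel the wall, XTH19 rose by 1.38 (SE 0.13) and EXPA15 fell by 0.97 (SE 0.15), both on the log2 scale. The other members, among them XTH18 at 0.72, EXPA9 at 0.50 and EXPA8 at -0.26, did not pass, the list's median was 0.06, and its camera test gave an adjusted p of 0.606. Adjusted over the list alone, 4 of these 7 genes passed. These 2 lists were the ones with at least 5 tested members, and neither passed. With dim probe sets kept, 1 list passed, that of auxin response (7 tested members, mean log2 fold change 0.54, camera, adjusted p = 0.0208).

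Genes that mark tissues or serve as references did not pass the test. For the root markers the log2 fold change was -0.04 for PYK10, 0.18 for NAI2 and 0.18 for JAL33. For the stomatal lineage it was -0.61 for SPCH, -0.51 for FMA (FAMA) and -0.26 for STOMAGEN, and for the phloem sugar transporter SWEET11 it was -0.31. The photosynthesis genes RCA and LHCB4.1 stood at -0.16 and -0.09, the mitotic kinase genes AUR1 and AUR2 at -0.26 and -0.51, and the cellulose synthesis gene COB at -0.06. Of 3 tested genes of the unfolded protein response, the regulator BZIP60 stood at 0.44, ATERDJ3B at -0.16 and CRT1b at -0.24, with a median of -0.16. The root hair expansin genes EXPA7 and EXPA18 stood at 0.16 and 0.22. Of other list genes that did not pass, the defence regulator gene WRKY22 stood at 0.61, the Casparian strip receptor gene GSO1 at 0.54, the iron regulator genes BHLH101 and PYE at 0.32 and -0.46, the secretion genes KEU and TPLATE at 0.31 and 0.05 and the clock gene GI at 0.24. Of lists with 1 or 2 tested members, GUT2, HCT, AT5G48570, UGT78D2 and DFR, stood at -0.14, -0.06, 0.03, -0.15 and 0.08. The reference genes PEX4, AT4G34270 and AT2G28390 stood at 0.21, 0.05 and 0.03. Of the 38 lists, 23 had between 1 and 4 tested members and 13 had none.

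The 2189 changed probe sets were 16% of those tested, their median absolute log2 fold change was 0.74, and 364 were higher and 222 lower by at least 2-fold. Of all changed probe sets, 53.2% were higher, against 48.5% when each array's median was set equal. A single gene name was attached to 1025 of them, 1131 had none in the probe annotation used here, and of the 71 that changed at least 4-fold, 45 were unnamed. No probe set carried the name of EXO70A1, so its level is not reported here and does not check the genotype labels. Without exo70A1-2 replicate 2, 577 probe sets were higher and 396 lower, and with a variance prior that ignores intensity 679 were lower.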

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

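The alternatives were planned before the data were examined, except counting named probe sets only, the lists chosen from the largest changes, the counts of changed list and family members and the other splits of the arrays, which were chosen after the result was seen. Of the 34 named genes 32 passed wherever tested, all but WES1 and GID1B. None reversed, but their arrays lay apart by genotype, so leaving 1 out could reverse none. The cause of differences between settings was not tested unless stated. The number of probe sets higher in exo70A1-2 ranged from 577 to 1696, and the number lower from 396 to 1347, when 1 array was left out, the lone array of a genotype then being assumed to vary like the others. Both lowest counts were found without exo70A1-2 replicate 2, which kept 43.4% of the changed probe sets. With the replicate number as a block, 2168 were higher and 2098 lower. The labels do not say what arrays of the same number share. Across the tested probe sets, the difference of replicate 1 and replicate 2 correlated at 0.28 between the genotypes. A factor shared by arrays of the same number therefore stays possible. With only 2 arrays per genotype and no label for it, the numbers are not taken as pairs in the main fit. The block changed the call of 0 named genes. With it 24 of the planned list members changed, against 10, 11 starvation members rose, against 7, and 9 of the EXO70A1 neighbours changed, against 5; it also gave 4 wound and touch members, 4 tubulin and 3 CRR genes that fell, against 1 each, 5 tetraspanin genes that rose, against 3, and 20 plastid-encoded genes that changed, against 2. Without the intensity trend, 679 were lower, 4 starvation members rose, 0 tubulin and 2 CRR genes fell and 3 neighbours changed. With no filter 1 tetraspanin gene rose and 3 neighbours changed. The share of all named genes that changed was 10.1% without the trend and 5.6% with no filter, against 14.1% in the main fit. By construction, a threshold of 0.10 gave 1599 lower, a fold of at least 2 gave 364 higher and 222 lower, and named probe sets alone gave 550 higher and 475 lower. With no filter 1 gene list passed, since more members were tested. The mean of the starvation-induced catabolism list was 0.59 and passed in all settings but camera with an estimated correlation (adjusted p = 0.168), as did the mitochondrial dysfunction list (0.278) where it had enough members. Of the 3 splits of the 4 arrays into pairs, 1, the real one, gave 2189 calls and the highest of the others 0. The other splits mix the genotypes in each group, which widens the spread within groups, so their 0 calls are no reference for 2189. Also, 3 splits are too few for a share under 0.05. EXO70A1 has no value under any setting. Noisy MAS5 values near background limit the dim genes.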

Other observations

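Gene families, grouped by symbol, and 3 lists drawn from the largest changes were chosen after the result was seen, and the tests of label fields were chosen after an uninformative one had been run.

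The 8 tested ATG genes, of autophagy, the recycling of cell contents in the vacuole, were ATG8 genes except for ATG3. Of these 4 rose in exo70A1-2, and 3 without the intensity trend. They were ATG8E with a log2 fold change of 1.09 (SE 0.16), ATG8B with 1.03, ATG8F with 0.69 and ATG8C with 0.50. ATG8D stood at -0.33, ATG8G at -0.01, ATG8H at 0.26 and ATG3 at 0.14, and none of these passed. Autophagy genes other than ATG8 were thus hardly covered. Of 7 tetraspanin genes, which encode membrane proteins, TET5 rose by 0.75, TET6 by 0.75 and TET3 by 0.59, but the number that rose was 0 without exo70A1-2 replicate 1, 1 without exo70A1-2 replicate 2 and 5 without Col-0 replicate 2. TUB9, a beta-tubulin gene, fell by 0.43, a call lost on leaving out exo70A1-2 replicate 1 or replicate 2, and CRR42, a gene of the chloroplast NDH complex pathway, fell by 0.89. As groups, each of these 4 families missed the threshold over the 32 families tested (camera, adjusted p = 0.0614, and 0.936 with an estimated correlation). Their medians kept their sign under both other scalings, which shifted them too little to change it, so this decides nothing about scaling. Of 68 tested plastid-encoded genes, 1 rose and 1 fell, against 8 and 7 without Col-0 replicate 2 and 3 and 2 without Col-0 replicate 1.

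The first hypothesis is that genes of carbon and amino acid starvation are higher in exo70A1-2 as a group, since GAT1_2.1 and SAG29 were among the largest rises. The list held 43 genes, those already seen being left out, and 15 were tested. The planned list of senescence and sugar starvation had 0 of 13 genes tested. Of the 15 tested members 7 rose (4 without the intensity trend) and 0 fell. Those that rose included AKINBETA1, a subunit of the SnRK1 energy kinase, by 1.16, MCCB of leucine breakdown by 0.93, and AT4G33150 of lysine breakdown by 1.00. As a group these members passed (camera, adjusted p = 6.45e-06 over the 3 lists). With an estimated correlation the call is lost (camera, adjusted p = 0.168), so it rests on the preset correlation. With 4 arrays the estimated form has few degrees of freedom and cannot decide whether correlation between genes explains the shift. After quantile normalization the list's median lay 0.75 above that of all tested genes. A uniform shift of an array cancels from this difference, and the trimmed means were already equal, so the value decides nothing about scaling. Among the 4 pairs of 1 mutant and 1 Col-0 array the list's median ran from 0.35 to 0.94. This range argues against a single array as the whole cause. Without Col-0 replicate 1 the list's mean was 0.48, and without Col-0 replicate 2 it was 0.70. A difference in plates or harvest cannot be told apart from genotype, since 0 label fields name them, so a starvation response may be a candidate explanation but its origin is open.

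The second hypothesis is that genes of the mitochondrial dysfunction response are higher as a group, since AT2G21640 and AT5G09570 were among the largest rises. Of 24 genes in this list 7 were tested, and 3 of these rose, AT2G41730 by 1.45, AT1G05340 by 1.12 and AT5G43450 by 0.91. NDB2 at 0.13 did not pass. The list passed (camera, adjusted p = 0.00386), but an estimated correlation ended the call (adjusted p = 0.278). With 4 arrays that form of the test decides little. The relative median was 0.40 after quantile normalization, which decides nothing about scaling, for the reason given for the starvation list. The list medians of the 4 pairs of arrays ran from 0.17 to 0.67. The lowest was below the median absolute log2 difference between the Col-0 arrays, 0.19. On 7 genes it therefore does not decide whether a single array moved the list. Plates or harvest stay open here too, with 0 label fields, so a mitochondrial signal may be present, on few genes.

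The third hypothesis is that rapid wound and touch genes are lower as a group, since ORA47 and STZ were among the falls. The list held 48 genes, of which 12 were tested. Of these AT1G19380 rose by 1.21 and AT1G72900 fell by 0.90. Over all 4 arrays the list did not pass (camera, adjusted p = 0.501). Its mean of -0.11 had a 95% interval over members from -0.47 to 0.26, which does not exclude a shift within it. The outcome turned on the Col-0 arrays, since without replicate 1 the mean was -0.29, 4 members fell and the list passed (adjusted p = 0.0457), while without replicate 2 the mean was 0.08 (adjusted p = 0.661), within a range up to 0.866 with no filter. The relative median of -0.072 after quantile normalization decides nothing about scaling for so small a shift, and a single array (list medians of the pairs from -0.22 to 0.093) and plates or harvest (0 label fields) stay open. ORA47 and STZ passed as falls under every alternative both were tested in. Since the tested members leave both out and the list's test is undecided, it does not say whether such a response accounts for their falls.

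A block of changed genes around the EXO70A1 locus was also tested, as a tightly linked difference between the lines would give. Of the 20 nearest tested named genes 5 changed, 25% with an exact 95% binomial interval from 8.66% to 49.1%, against 14.1% of all 7213 named genes tested. Fewer neighbours changed on leaving out exo70A1-2 replicate 1, exo70A1-2 replicate 2 or Col-0 replicate 1. The share of all named genes that changed was lower in these settings as well. With the replicate number as a block 9 changed, 45% with an interval from 23.1% to 68.5%, against 28.5% of all named genes. Both intervals hold the share over all genes. With the block, and with the filter at the 60th percentile (5 of 16, up to 58.7%), the interval does not lie below a majority. The test was set for a majority of changed neighbours, so a linked difference that changed fewer of them is not excluded under any setting.

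Control probe sets were not part of the comparison. The signal of the 25S ribosomal RNA control was 218 on Col-0 replicate 2 and between 654 and 876 on the other arrays, and the cre spike control was 6299 on Col-0 replicate 1 and between 3136 and 3709 on the others. None of the 64 controls passed in limma, the smallest adjusted p being 0.106.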
